A study of Mus musculus with 7 samples.

How the data were processed

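Total RNA of 7 tumours was extracted with RNeasy Plus Mini columns, and the libraries were made with a NEBNext Ultra kit, per the labels' protocols. The cells had been kept for 10 to 15 passages before they were implanted. The series describes 4 GSC1 and 3 GSC2 tumours as independent, and groups and replicate numbers were taken from the sample titles. The deposited values are raw read counts per Ensembl mouse gene, 1 table per tumour, which the authors made with TopHat2 2.0.11 and HTSeq, per the submitters' processing notes. Those notes name the builds mm9 and dm3 without saying what each was used for. The HTSeq version, counting mode and strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart and such genes are uncertain.

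Each table held 37620 gene identifiers and 5 summary lines, which were left out of library sizes and tests. Reads on no gene made up 6.19 to 14.2% of all reads listed in a library, reads without a unique position 12.8 to 21.0%, and ambiguous reads 0.357 to 0.460%. The counts on genes were 32643408, 27067443, 27696955 and 21635117 in GSC1 replicates 1 to 4 and 18643155, 27020814 and 20904113 in GSC2 replicates 1 to 3. A reference annotation of a later build gave symbols for 32897 identifiers, and the other 4723 carried 0.485% of the counts. It also gave transcript lengths, as the longest transcript of a gene, for 97.2% of the genes tested. No coordinates were used. Every pair of libraries differed by more than sampling noise, with a chi-square of at least 66.5 per degree of freedom.

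Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM factors, genes kept by filterByExpr (16068), a robust quasi-likelihood fit and test of GSC2 against GSC1, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values are counts over TMM-scaled library sizes. Gene lists were tested with camera in limma 3.58.1 on a preset correlation of 0.01, adjusted over 40 lists. The lists (797 genes, of which 785 were in the tables), the tests, the first set of alternatives and the rule for named genes were fixed before the data were examined. Separation of the lines was the mean Euclidean distance between tumours of different lines minus that within lines, over log2 CPM of the 500 most variable genes with a prior count of 2, with an exact permutation test over 35 splits. Correlations with the brain score were tested exactly over 5040 pairings, and within lines over 144 arrangements, in Python 3.11.15 with scipy 1.17.1.

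The alternatives fixed beforehand were RLE and upper-quartile factors, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, the replicate number as a block, a host score from the myeloid and endothelial lists as a covariate, an estimated correlation and fry for the lists, and each tumour left out in turn. After seeing the data a brain score was added as a covariate, the mean of the neuron and mature oligodendrocyte list scores. A loess trend on transcript length per library was added as an offset, alone and with the brain score, as was a fit without the 3 libraries with the most negative length slope. The brain score is measured in the same tumours, so the fits with it describe differences at equal score and are no independent test.

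The rule named the genes of the line labels, the 8 genes per direction with the largest fold among those that passed, did not overlap between the lines and reached a mean of 5 CPM, Efnb2 with its receptors, and up to 4 genes per list by smallest adjusted p, with predicted-gene names left out of the second group. No gene passed the main test, so the second part of the rule was applied to the fit with the brain score, a choice made after seeing the data. Genes named outside the rule are said to be so, and results for some genes are not reported here.

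The tests were run on simulated counts for 16068 genes. The main test recovered 0% of 50 genes changed 2-fold, 30% changed 4-fold, 62% changed 8-fold and 88% changed 16-fold, with 2 false calls. With tumours that differed in brain score it recovered 0, 32, 66 and 80%, with 0 false calls. On the latter tumours the fit with the covariate recovered 40, 98, 98 and 100%, with 14 false calls. Those tumours were drawn from a fit on the brain score. Differences in the length trend or in brain region were not simulated, so recovery and false calls may differ in the real tumours. Camera found a list shifted 2-fold at an adjusted p of 7.18e-26, or 0.0115 with an estimated correlation, and called 0 other lists. The simulated genes were drawn independently of each other, so this cannot show how often camera calls lists whose genes vary together. In the tumours the estimated correlation was 0.946 for the mitosis list and 0.974 for the mature oligodendrocyte list.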

Results

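RNA was sequenced from 7 brain tumours that grew in nude mice after mouse glioblastoma stem-like cells had been implanted into the brain. The cells descended from neural stem cells of the subventricular zone, the germinal layer along the lateral ventricles, and existed as 2 lines. GSC1 carried the changes labelled lgT and Ras, and GSC2 carried a short hairpin against p53, loss of Nf1, which encodes a negative regulator of Ras, and CDK4. There were 4 independent GSC1 tumours and 3 independent GSC2 tumours, each with 1 library of 18643155 to 32643408 reads counted on genes. The comparison asked how GSC2 tumours differed from GSC1 tumours. Each combination of changes was present in 1 line, so the comparison is one of lines. Log2 fold changes are GSC2 minus GSC1, and levels in CPM, read counts scaled by TMM-adjusted library size, are means ± SD with n = 4 for GSC1 and n = 3 for GSC2.

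Tumours of the same line differed from each other about as much as from those of the other line. Mbp, the gene for a main protein of myelin, was at 582, 221, 5870.1 and 2500.4 CPM in GSC1 replicates 1 to 4 and at 938, 2939 and 3826 CPM in GSC2 replicates 1 to 3. Clic5, a chloride intracellular channel gene, came closest to separating the lines, at 3.62 ± 1.34 CPM in GSC1 and 56.7 ± 6.16 CPM in GSC2 (log2 fold change 3.97, SE 0.35, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0801). Itga8, the integrin alpha 8 gene, was at 3.44 ± 1.12 CPM in GSC1 and 33.7 ± 5.27 CPM in GSC2. None of the 16068 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. An unadjusted p under 0.05 was found for 677, limma-voom called 1 gene and DESeq2 called 192. The values of the lines did not overlap for 897 genes, which is 5.58% of those tested, where chance gives 5.71%. The mean distance between tumours of different lines exceeded that between tumours of the same line by 3.04 (69.2 against 66.2, in log2 CPM over the 500 most variable genes; one-sided exact permutation p = 0.371 over 35 splits).

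Markers of normal brain cells varied widely between the tumours. A brain score, the mean log2 CPM over the neuron and mature oligodendrocyte lists, was 5.60, 4.36, 7.83 and 7.14 in GSC1 replicates 1 to 4 and 5.81, 7.21 and 6.997 in GSC2 replicates 1 to 3. Over the 7 tumours 5758 genes followed this score, 3146 with it and 2612 against it. The astrocyte list, which shares no gene with the score, rose with it (Pearson r = 0.967, exact permutation p = 0.000595, adjusted p = 0.0226, Spearman rho = 0.964, exact permutation p = 0.00278, adjusted p = 0.0823, and r = 0.945 without the 2 tumours farthest from the median score). The mitosis list fell as the score rose (Pearson r = -0.865, exact permutation p = 0.0123, adjusted p = 0.0425, Spearman rho = -0.857, exact permutation p = 0.0238, adjusted p = 0.0823, and r = -0.862 without the 2 tumours farthest from the median score). These are among 38 lists related to the score, and the Spearman values did not pass after adjustment. With scores centred within each line and permuted within lines (144 arrangements), a test added after seeing the data, r was 0.979 for the astrocyte list (exact permutation p = 0.00694, adjusted p = 0.0880) and -0.970 for the mitosis list (exact permutation p = 0.0139, adjusted p = 0.0880). The rank correlations within lines were 1 (exact permutation p = 0.0139, adjusted p = 0.0880) and -0.857 (exact permutation p = 0.0833, adjusted p = 0.167). None of the 38 relations passed within lines after adjustment.

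**Figure D1:**
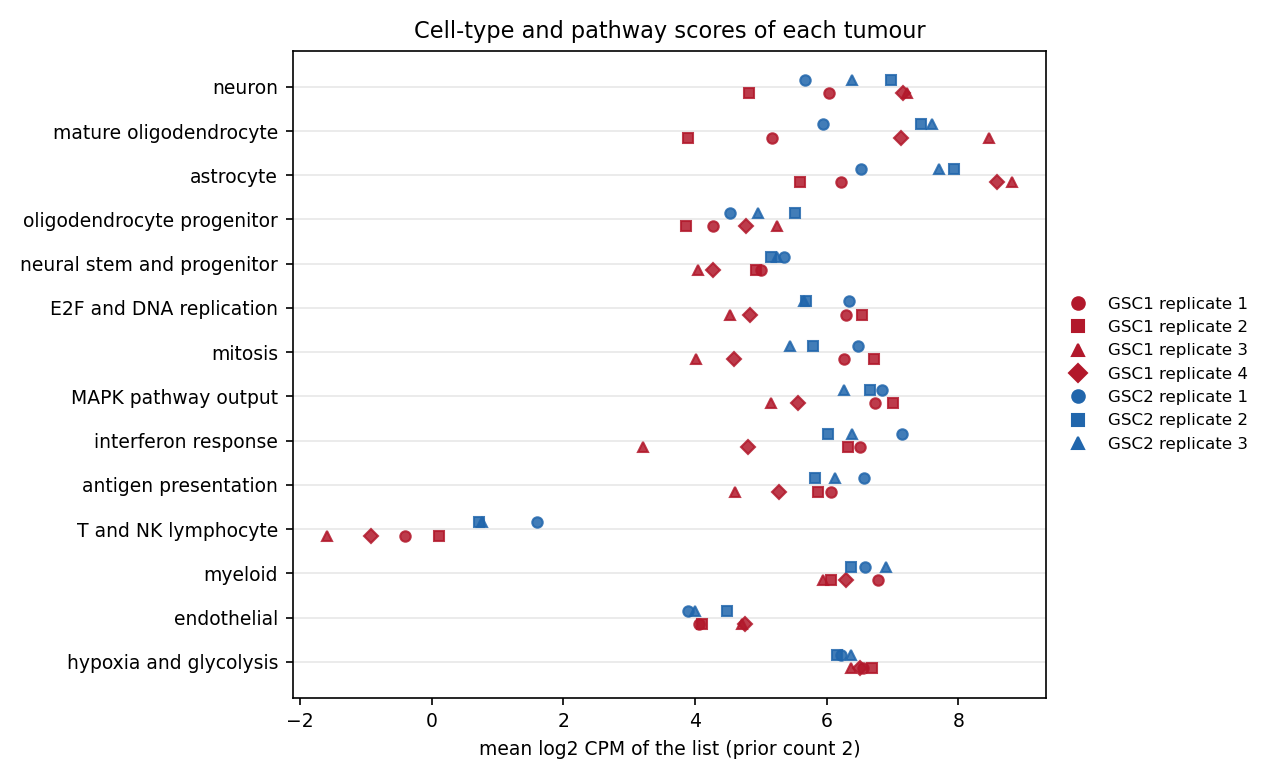
Score of 14 gene lists in each tumour, as mean log2 CPM on the horizontal axis, with GSC1 tumours in red, GSC2 tumours in blue and 1 symbol shape per replicate number. GSC1 replicates 3 and 4 have the highest astrocyte scores, 8.81 and 8.58, and the lowest mitosis scores, 4.01 and 4.59.

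The brain region whose genes were present differed from tumour to tumour. Cbln3, a gene of cerebellar granule cells, was at 245 CPM in GSC1 replicate 4, with Gabra6 at 115 CPM and Pcp2, a Purkinje cell gene, at 67.5 CPM. In the other tumours Cbln3 reached at most 1.31 CPM, Gabra6 1.15 CPM and Pcp2 0.0397 CPM. Hindbrain and spinal cord genes were high in GSC1 replicates 3 and 4, with Hoxb5 at 209 and 49.6 CPM and Slc6a5, the neuronal glycine transporter gene, at 135 and 81.2 CPM. The other 5 tumours had at most 0.0501 CPM of Hoxb5 and 1.89 CPM of Slc6a5. Ddn, a gene of forebrain dendrites, was at 2.66 and 0.762 CPM in GSC1 replicates 3 and 4 and between 47.9 and 152 CPM in the others. Ttr, the transthyretin gene of the choroid plexus, was at 3.01, 0.551, 28.7 and 8165 CPM in GSC1 replicates 1 to 4 and at 2026, 2649.9 and 4579 CPM in GSC2 replicates 1 to 3. These genes, and Mbp, were chosen after values in the tumours had been seen.

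**Figure D2:**
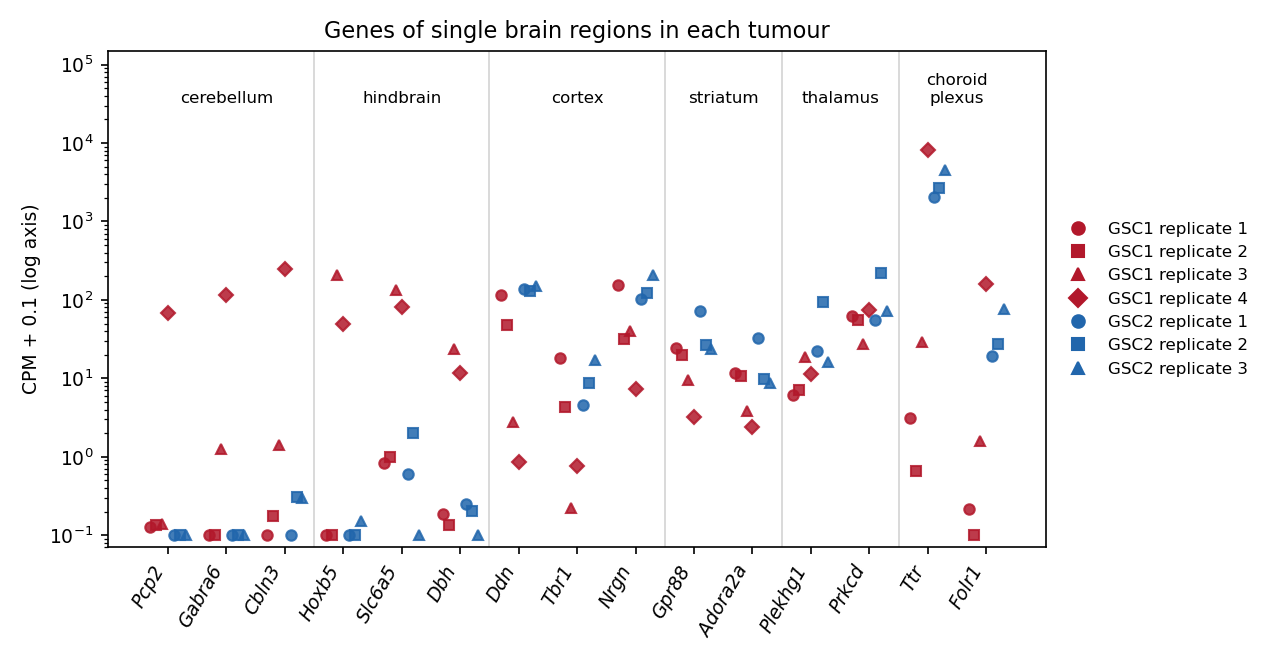
CPM plus 0.1 of genes that mark single brain regions, on a log axis, with 1 symbol per tumour (GSC1 red, GSC2 blue). Cbln3 stands at 245 CPM in GSC1 replicate 4, and Hoxb5 at 209 and 49.6 CPM in GSC1 replicates 3 and 4.

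Transcript length set 3 libraries apart. In GSC1 replicate 3, GSC1 replicate 4 and GSC2 replicate 3 the median log2 deviation of genes with transcripts of at least 8000 bases minus that of genes of at most 2000 bases was -0.40, -0.36 and -0.70. It lay between 0.02 and 0.64 in the other 4. Mki67, a proliferation marker with a transcript of 10061 bases, was at 3.18, 5.67 and 8.82 CPM in these 3 libraries and between 84.8 and 231 CPM in the others. Ube2c, a mitotic gene with a transcript of 2191 bases, was at 28.9, 41.5 and 93.9 CPM in the 3 and between 77.6 and 131 CPM in the others. Mki67 and Ube2c were chosen after their values were seen, and the 3 libraries are called the short-biased libraries from here on. A fit without them also leaves out GSC1 replicates 3 and 4, with brain scores of 7.83 and 7.14. It compares GSC1 tumours at scores of 5.60 and 4.36 with GSC2 tumours at 5.81 and 7.21. Effects of transcript length and of brain score therefore cannot be told apart in that fit.

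With the brain score as a covariate, a step chosen after seeing the data, 114 genes differed between the lines, 84 higher in GSC2 and 30 higher in GSC1. The values of the lines did not overlap for 54 of the 84 and for 24 of the 30. Clic5 (log2 fold change 3.98, SE 0.31, edgeR quasi-likelihood adjusted p = 0.00601) and Itga8 (3.46, SE 0.24, adjusted p = 0.00323) were higher in GSC2. So were Rsad2, an antiviral gene induced by interferon (3.16, SE 0.40), Usp44 (3.04, SE 0.51), the antiplasmin gene Serpinf2 (2.99, SE 0.45), Calcb (2.98, SE 0.49) and Lrrc10b (2.96, SE 0.50). Higher in GSC1 were, among others, the Eph receptor gene Epha3 (-3.35, SE 0.53), the retinol carrier gene Rbp4 (-2.96, SE 0.38), the Wnt-induced matricellular gene Ccn4 (-2.90, SE 0.47), Klhl1 (-2.52, SE 0.26), the acid phosphatase gene Acpp (-2.31, SE 0.28) and the matrix protease gene Adamts8 (-2.31, SE 0.26). Nxph4 was called as well (-3.38, SE 0.48), but it was far higher in GSC1 replicates 3 and 4 than in the other GSC1 tumours, with 6.09, 6.43, 67.7 and 57.8 CPM in GSC1 replicates 1 to 4 and 2.39, 3.37 and 2.56 CPM in GSC2 replicates 1 to 3. The pseudogene Rps26-ps1 had the largest fold among the genes named by the rule, at 2.73 ± 4.25 CPM in GSC1 and 85.5 ± 28.8 CPM in GSC2 (7.16, SE 0.46), but it can share reads with other copies of Rps26, so its level is uncertain.

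The count of 114 rested on single tumours. It was 51, 6, 10 and 69 without GSC1 replicate 1, 2, 3 and 4, and 1, 68 and 119 without GSC2 replicate 1, 2 and 3. It was 12 in a test against a 1.5-fold change, 1282 in DESeq2 with the same covariate, and 309 with the length trend of each library removed as well, 110 of the 114 among them and all 110 in the same direction. Without any covariate and without the 3 short-biased libraries 55 genes differed, of which 15 were among the 114. The fits share 4 tumours, so this overlap is no independent evidence. Clic5, Itga8, Epha3 and Acpp were among the 15, as were the imprinted gene Mest and Tgfb3, the gene for transforming growth factor beta 3.

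**Figure D3:**
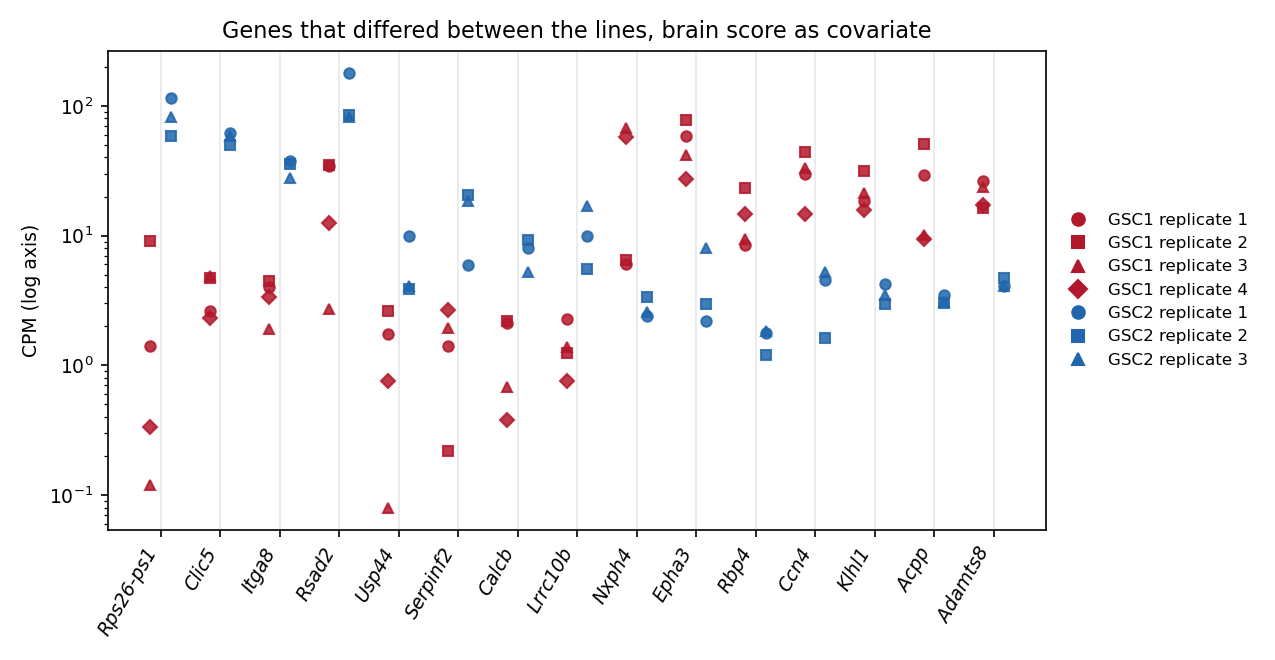
CPM on a log axis of genes among the 8 per direction with the largest fold in the fit with the brain score as a covariate, with 1 symbol per tumour (GSC1 red, GSC2 blue). Clic5 lies between 2.33 and 4.85 CPM in GSC1 tumours and between 49.8 and 61.5 CPM in GSC2 tumours.

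None of the genes that the line labels concern passed the test between the lines. Trp53 was at 221, 236, 77.2 and 84.8 CPM in GSC1 replicates 1 to 4 and at 191, 113 and 127 CPM in GSC2 replicates 1 to 3 (log2 fold change -0.11, SE 0.47). Nf1 was at 96.5, 163, 113 and 89.7 CPM in the GSC1 tumours and at 137, 142 and 70.3 CPM in the GSC2 tumours (0.01, SE 0.33). Cdk4, the gene for a kinase that phosphorylates the retinoblastoma protein, was at 574, 540.3, 252 and 295 against 609, 328 and 472 CPM (0.18, SE 0.38). Hras (-0.30, SE 0.30) and Nras (0.04, SE 0.32) did not pass either. The list of 6 genes had a camera adjusted p of 0.963, and 0 passed adjusted over the list alone. Gene totals do not show a deleted part of a gene or a transgene from another species. Host cells may add their own reads, a share that was not measured, so these values do not check the labels.

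Efnb2, the gene for the ligand ephrin-B2, was at 86.2 ± 46.1 CPM in GSC1 and 78.8 ± 31.4 CPM in GSC2 (log2 fold change -0.13, SE 0.49). Among Eph receptor genes, Epha3 was at 51.3 ± 21.6 against 4.40 ± 3.16 CPM, Epha4 at 21.5 ± 3.62 against 69.6 ± 25.4 CPM, Ephb2 at 11.1 ± 0.700 against 22.7 ± 2.59 CPM and Epha7 at 9.30 ± 2.57 against 27.4 ± 13.1 CPM. Ephb3 was at 17.5 ± 6.42 against 27.3 ± 4.93 CPM and Ephb4 at 57.9 ± 31.0 against 55.4 ± 13.7 CPM. Of the 21 Eph receptor and ephrin genes tested, 5 passed adjusted over the list alone, 3 higher in GSC2 and 2 higher in GSC1. Over all genes 0 passed edgeR's test (6 at an unadjusted p under 0.05) or limma-voom, DESeq2 called 4, Epha3 and Epha4 among them, and edgeR called Epha3 without the 3 short-biased libraries. Epha4 (1.57, SE 0.24, adjusted p = 0.0407) and Epha3 (adjusted p = 0.0435) passed over all genes with the brain score as a covariate, and Ephb2 had an adjusted p of 0.0560. The list had no shared direction (camera adjusted p = 0.991), and the test for change in either direction, fry's mixed test, gave an adjusted p of 0.0176.

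Of the 40 gene lists 24 passed camera with a preset correlation, 17 toward GSC2 and 7 toward GSC1. With a correlation estimated from the data 0 passed, as with fry's directional test. The preset correlation also gave 3 to 24 lists in every other split of the tumours into 4 and 3. Over all genes and without a covariate, 0 of the 732 list members tested passed edgeR's quasi-likelihood test (84 at an unadjusted p under 0.05) and 0 passed limma-voom, while DESeq2 called 32, 18 higher in GSC2 and 14 higher in GSC1. Without the 3 short-biased libraries edgeR called 10, of which 5 were members of the choroid plexus and ependyma list, Ttr among them. All 5 were highest in GSC1 replicate 4, which that fit leaves out. Counts adjusted over a list alone are from edgeR. The lists that kept call and direction in every preset-correlation setting that could test them were 5: T and NK lymphocyte and Hedgehog pathway, called toward GSC2, and mesenchymal glioblastoma, extracellular matrix, and hypoxia with glycolysis, called toward GSC1. In the Hedgehog list only 5 of 11 folds were positive.

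**Figure D4:**
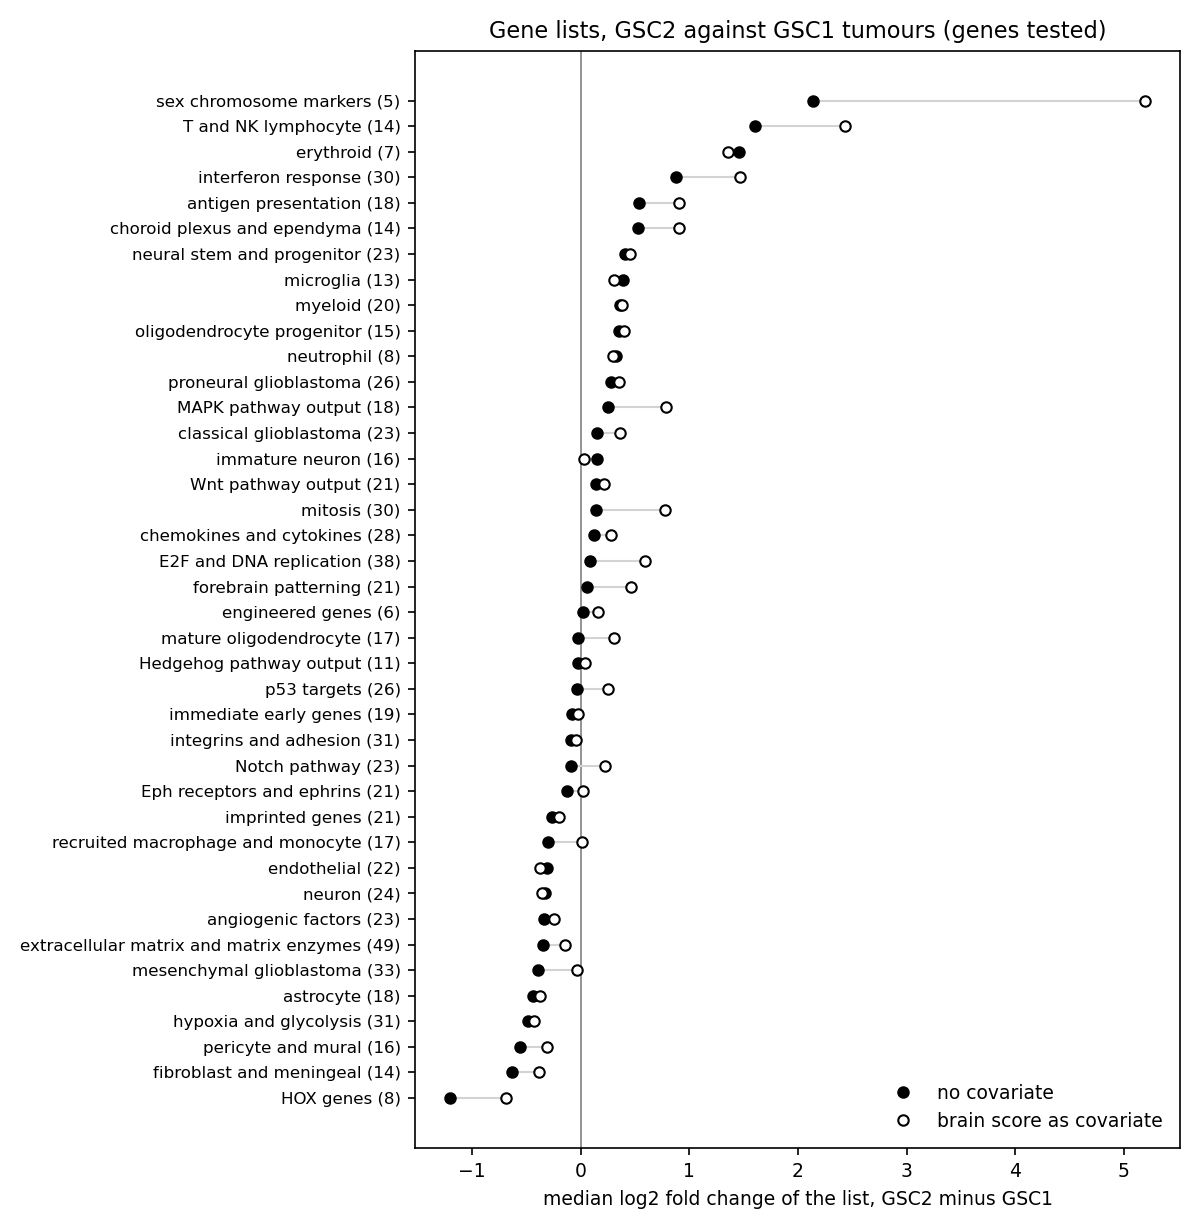
Median log2 fold change, GSC2 minus GSC1, of the 40 gene lists without a covariate (filled) and with the brain score as a covariate (open). The interferon list moves from 0.87 to 1.46 and the mitosis list from 0.14 to 0.78.

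Feedback and output genes of the MAPK cascade, which acts below Ras, were called toward GSC2 as a list, with a positive fold in 13 of 18 (camera adjusted p = 0.000791, and adjusted p = 0.566 with an estimated correlation). The list score was 6.73, 7.01, 5.15 and 5.56 in GSC1 replicates 1 to 4 and 6.84, 6.66 and 6.27 in GSC2 replicates 1 to 3. Only GSC1 replicates 3 and 4 lay under all GSC2 tumours. Spry1, an inhibitor of receptor tyrosine kinase signals, was at 42.6 ± 19.5 CPM in GSC1 and 154 ± 51.3 CPM in GSC2, Spry2 at 79.3 ± 23.9 against 151 ± 29.9 CPM, and Etv5, an ETS factor induced by this cascade, at 134 ± 65.7 against 275 ± 60.2 CPM. Of the 18, 2 passed adjusted over the list alone, both higher in GSC2. Over all genes edgeR and limma-voom called 0 (4 at an unadjusted p under 0.05 in edgeR) and DESeq2 called Spry1 and Epha4. With the brain score as a covariate 4 passed over all genes and 10 adjusted over the list alone, the 4 being Spry1 (2.09, SE 0.25), Spry2 (1.09, SE 0.15), Etv5 (1.35, SE 0.15) and Epha4. As a list they did not pass in that fit with an estimated correlation (camera adjusted p = 0.344). The list was not called without GSC1 replicate 3 (adjusted p = 0.368), without GSC1 replicate 4 (0.0968) or without the 3 short-biased libraries (0.261). The p53 targets went both ways, 12 positive and 14 negative (camera adjusted p = 0.979), with the apoptosis gene Bax at 54.4 ± 13.9 against 75.7 ± 14.7 CPM and Phlda3, an Akt inhibitor gene, at 92.9 ± 15.1 against 54.1 ± 5.84 CPM.

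In the Hedgehog list the co-receptor genes Cdon and Gas1, and also Gli2, were higher in GSC2 and the target gene Gli1 was not. Cdon was at 16.9 ± 5.06 CPM in GSC1 and 73.2 ± 31.4 CPM in GSC2, Gas1 at 45.6 ± 8.68 against 131 ± 39.6 CPM and Gli2 at 5.28 ± 1.62 against 17.7 ± 10.2 CPM, while Gli1 was at 2.49 ± 1.09 against 1.21 ± 0.240 CPM. The list passed toward GSC2 (camera adjusted p = 0.00270, and adjusted p = 0.148 with an estimated correlation) with a mean fold of 0.35 and a median of -0.03 over 11 genes, so median and test differ in sign. Folds were positive in 5 and negative in 6 of the 11. There were 3 genes that passed adjusted over the list alone, all higher in GSC2. With the covariate Cdon (2.21, SE 0.28) and Gas1 (1.61, SE 0.22) passed over all genes.

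Neural stem and progenitor genes were higher in GSC2, with 18 of 23 positive (camera adjusted p = 2.85e-05, and adjusted p = 0.148 with an estimated correlation). Sox2 was at 103 ± 38.2 CPM in GSC1 and 164 ± 34.4 CPM in GSC2, the Notch effector gene Hey1 at 53.1 ± 16.98 against 91.8 ± 11.5 CPM, and Prom1, the gene for CD133, at 12.5 ± 3.16 against 22.2 ± 5.54 CPM. Emx2, a forebrain homeobox gene at 10.5 ± 9.28 against 32.8 ± 12.1 CPM, passed with the brain score as a covariate (2.61, SE 0.39). The proneural glioblastoma list had 20 of 26 positive (camera adjusted p = 0.00919, and adjusted p = 0.506 with an estimated correlation) and the oligodendrocyte progenitor list 12 of 15 (camera adjusted p = 0.0141, and adjusted p = 0.533 with an estimated correlation), with Nkx2-2 at 4.87 ± 2.91 against 9.63 ± 2.56 CPM, Ptprz1 at 114 ± 51.1 against 191 ± 64.9 CPM and Olig2 at 48.3 ± 8.15 against 61.7 ± 15.5 CPM. The classical glioblastoma list had 14 of 23 positive (camera adjusted p = 0.0353, and adjusted p = 0.533 with an estimated correlation), although Tgfb3 was at 419 ± 305 against 68.3 ± 18.5 CPM and Meis1 at 23.7 ± 1.62 against 9.14 ± 2.69 CPM. Adjusted over the list alone 0 genes of the first 3 lists passed and 5 of the classical list, 3 higher in GSC2 and 2 higher in GSC1. Without the 3 short-biased libraries the stem cell list was not called (adjusted p = 0.293), nor the classical list (0.925). The oligodendrocyte progenitor list was lost without GSC1 replicate 1 (0.0760), GSC1 replicate 2 (0.191) or GSC2 replicate 2 (0.499), the proneural list without GSC2 replicate 2 (0.239). The oligodendrocyte progenitor list was also not called with the brain score as a covariate (0.0844) or with the length offset added to it (0.117), nor the classical list with the length offset (0.0671) or both (0.125). The classical list was lost without GSC1 replicate 3 (0.248), GSC1 replicate 4 (0.403), GSC2 replicate 1 (0.0591) or GSC2 replicate 2 (0.164).

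Interferon-stimulated genes were higher in GSC2, with a positive fold in 29 of 30 and a median of 0.87 (camera adjusted p = 5.45e-14, and adjusted p = 0.506 with an estimated correlation). Cxcl10, a chemokine gene induced by interferon gamma, was at 28.3 ± 17.2 CPM in GSC1 and 116 ± 42.3 CPM in GSC2, Rsad2 at 21.3 ± 16.2 against 116 ± 56.0 CPM, the GTPase gene Irgm1 at 106 ± 52.0 against 228 ± 93.5 CPM and Gbp2 at 57.6 ± 26.2 against 126 ± 58.5 CPM. The list score was 6.50, 6.33, 3.21 and 4.81 in GSC1 replicates 1 to 4 and 7.15, 6.01 and 6.38 in GSC2 replicates 1 to 3. No interferon gene (0) passed adjusted over the list alone. With the brain score as a covariate 6 passed over all genes and 27 adjusted over the list alone, all higher in GSC2, among them Cxcl10 (2.48, SE 0.32), Rsad2 and Irgm1 (1.40, SE 0.23). The estimated correlation between the list's genes without a covariate was 0.933, so the 27 are not separate results. With an estimated correlation the list did not pass in the covariate fit (camera adjusted p = 0.344). Irgm1 overlapped between the lines, at 149 and 151 CPM in GSC1 replicates 1 and 2 and 136 CPM in GSC2 replicate 2. Without the 3 short-biased libraries the list was not called (adjusted p = 0.347).

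Antigen presentation genes were higher in GSC2, with 16 of 18 positive (camera adjusted p = 1.24e-06, and adjusted p = 0.506 with an estimated correlation). The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 were at 13.5 ± 3.63, 17.8 ± 3.16 and 16.9 ± 4.06 CPM in GSC1 and at 33.4 ± 13.5, 36.8 ± 13.2 and 38.6 ± 13.9 CPM in GSC2, and Cd74, the gene for the invariant chain, at 77.5 ± 16.6 against 144 ± 28.99 CPM. Of these genes 4 passed adjusted over the list alone, all higher in GSC2, and over all genes 0 in edgeR (6 at an unadjusted p under 0.05), limma-voom or DESeq2. The list was not called without the 3 short-biased libraries (adjusted p = 0.567).

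Lymphocyte genes were higher in GSC2 and low in every tumour. In the T and NK lymphocyte list 12 of 14 had a positive fold, with a median of 1.60 (camera adjusted p = 2.20e-14, and adjusted p = 0.148 with an estimated correlation). Il2rb, the gene for the interleukin 2 receptor beta chain, was at 0.489 ± 0.387 CPM in GSC1 and 4.31 ± 2.81 CPM in GSC2, the cytotoxic granule gene Nkg7 at 0.308 ± 0.143 against 1.60 ± 0.885 CPM, Cd8a at 0.0494 ± 0.0430 against 0.851 ± 0.585 CPM and Cd2 at 0.0772 ± 0.0486 against 0.600 ± 0.176 CPM. Adjusted over the list alone 4 passed, all higher in GSC2, and with the brain score as a covariate Il2rb passed over all genes (adjusted p = 0.0362). Nude mice lack a thymus and most mature T cells. The myeloid list had 18 of 20 positive (camera adjusted p = 0.00216, and adjusted p = 0.533 with an estimated correlation) and the microglia list 9 of 13 (camera adjusted p = 0.0292, and adjusted p = 0.603 with an estimated correlation), with Ctss at 477 ± 129.8 against 659 ± 93.5 CPM, Fcer1g at 34.9 ± 12.3 against 51.1 ± 14.5 CPM and Siglech at 12.5 ± 4.59 against 22.2 ± 3.90 CPM. In these lists 0 members passed adjusted over the list alone. The myeloid list was lost without GSC1 replicate 3 (adjusted p = 0.0592) or GSC2 replicate 3 (0.302), and the microglia list without GSC1 replicate 2 (0.529), GSC2 replicate 2 (0.0853) or GSC2 replicate 3 (0.432). Without the 3 short-biased libraries neither was called (myeloid adjusted p = 0.925, microglia adjusted p = 0.261). The microglia list was also not called with the brain score as a covariate (0.311) or with the length offset added to it (0.174).

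Matrix and mesenchymal genes were higher in GSC1. A negative fold was found in 36 of 49 extracellular matrix genes (camera adjusted p = 0.000791, and adjusted p = 0.148 with an estimated correlation) and in 25 of 33 genes of the mesenchymal glioblastoma list (camera adjusted p = 6.50e-05, and adjusted p = 0.512 with an estimated correlation). The thrombospondin genes Thbs1 and Thbs2 were at 54.9 ± 7.09 and 106 ± 34.0 CPM in GSC1 and at 18.9 ± 7.21 and 43.9 ± 2.39 CPM in GSC2. Timp1, a metalloproteinase inhibitor gene, was at 211 ± 58.1 against 105 ± 17.8 CPM and S100a11 at 151 ± 37.1 against 66.9 ± 6.94 CPM. Cebpd, which encodes a mesenchymal regulator, was at 33.0 ± 4.06 against 61.3 ± 12.1 CPM, the opposite direction. Adjusted over the list alone 3 mesenchymal genes passed, 2 higher in GSC1 and 1 higher in GSC2, and 0 matrix genes. Both S100a11 (-1.07, SE 0.18) and Tgfb3 of the classical list (-2.01, SE 0.25) passed over all genes with the brain score as a covariate, higher in GSC1. In that fit the median fold of the mesenchymal list moved from -0.39 to -0.03, with positive folds in 13 of 33 in place of 8, and that of the matrix list from -0.35 to -0.15, with positive folds in 21 of 49 in place of 13. Camera called both toward GSC1 in that fit (adjusted p = 0.0114 and 0.0117), but neither with an estimated correlation (0.472 and 0.357).

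The hypoxia and glycolysis list was called toward GSC1 as a whole, with a negative fold in 25 of 31 and a median of -0.48 (camera adjusted p = 2.85e-05, and adjusted p = 0.148 with an estimated correlation). Pkm was at 2238 ± 246 CPM in GSC1 and 1426 ± 161 CPM in GSC2, Tpi1 at 809.7 ± 92.2 against 509 ± 96.2 CPM and Ankrd37, a HIF target gene, at 4.82 ± 1.14 against 2.15 ± 0.169 CPM. Egln3, also a HIF target, was at 22.3 ± 7.42 against 41.8 ± 16.7 CPM. Adjusted over the list alone 0 passed.

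Vascular lists were also higher in GSC1, with negative folds in 20 of 22 endothelial genes (camera adjusted p = 0.00103, and adjusted p = 0.533 with an estimated correlation), 12 of 16 pericyte and mural genes (camera adjusted p = 0.00568, and adjusted p = 0.506 with an estimated correlation) and 11 of 14 fibroblast and meningeal genes (camera adjusted p = 0.0405, and adjusted p = 0.603 with an estimated correlation). Vwf was at 100.4 ± 46.7 CPM in GSC1 and 49.6 ± 17.2 CPM in GSC2, Pecam1 at 29.4 ± 7.50 against 21.9 ± 4.97 CPM, the pericyte receptor gene Pdgfrb at 55.2 ± 11.6 against 29.4 ± 8.56 CPM, and Col3a1 at 304 ± 119 against 164 ± 34.4 CPM. In the 3 lists 0 genes passed adjusted over the list alone. Without the 3 short-biased libraries the endothelial (adjusted p = 0.948) and pericyte lists (0.424) were not called and the fibroblast list was called toward GSC2 (0.00881). The pericyte list was lost without GSC1 replicate 3 (0.0866), GSC2 replicate 1 (0.0591) or GSC2 replicate 3 (0.0531), and the fibroblast list without GSC1 replicate 3 (0.540), GSC1 replicate 4 (0.651) or GSC2 replicate 1 (0.107). It was also lost with a mean of at least 5 CPM (0.0597) and with the length offset (0.0558).

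Cell cycle lists were called toward GSC2 by small folds. Of the mitosis genes 25 of 30 were positive, with a median of 0.14 (camera adjusted p = 0.00952, and adjusted p = 0.747 with an estimated correlation), and of the E2F and DNA replication genes 29 of 38, with a median of 0.09 (camera adjusted p = 0.0353, and adjusted p = 0.806 with an estimated correlation). Cdk1, the kinase gene of mitotic entry, was at 144, 172, 44.9 and 65.3 CPM in GSC1 replicates 1 to 4 and 184, 105 and 123 CPM in GSC2 replicates 1 to 3, and Plk1 at 72.0, 89.7, 19.2 and 34.8 against 91.0, 55.8 and 68.8 CPM. Cdkn2c, which encodes an inhibitor of CDK4 and CDK6, was at 43.4 ± 22.9 against 66.5 ± 14.3 CPM. No gene (0) of either passed adjusted over the list alone. With the brain score as a covariate 26 mitosis genes and 19 replication genes did, all higher in GSC2, but over all genes only 1 and 0 passed. With an estimated correlation neither list passed in that fit (camera adjusted p = 0.344 and 0.357). Neither list was called without GSC1 replicate 3 (mitosis adjusted p = 0.934, E2F adjusted p = 0.598), GSC1 replicate 4 (0.596 and 0.934) or GSC2 replicate 1 (0.541 and 0.979), and without the 3 short-biased libraries both were called toward GSC1 (0.00111 and 3.08e-05). The GSC1 tumours in that fit had brain scores of 5.60 and 4.36, under the 5.81 and 7.21 of the GSC2 tumours. Cell cycle genes fell as the score rose, so this reversal may follow the score.

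Lists of normal brain cells did not pass without a covariate: astrocyte, with 16 of 18 negative (camera adjusted p = 0.261), neuron, with 16 of 24 negative (0.963), and mature oligodendrocyte, with 9 of 17 negative (0.0533). For mature oligodendrocyte genes the mean fold was 0.07 and camera pointed toward GSC2, so sign count and test differ in direction. These calls depended on the setting. With the brain score as a covariate, which is built from the neuron and mature oligodendrocyte lists, astrocyte (0.00122) and neuron genes (0.00220) passed toward GSC1 and mature oligodendrocyte genes toward GSC2 (0.0334), and none of the 3 with an estimated correlation (0.474, 0.431 and 0.576). Holding the mean of the neuron and mature oligodendrocyte scores fixed sets their folds against each other, so these 2 calls are not separate results. The calls in the following settings all used the preset correlation. Mature oligodendrocyte genes also passed toward GSC2 with RLE factors (0.0413), no filter (0.0340), a mean of at least 5 CPM (0.0265) or the length offset (0.0307), and without GSC1 replicate 3 (1.23e-09), GSC1 replicate 4 (0.0214) or GSC2 replicate 1 (0.000199). Astrocyte genes passed toward GSC1 without GSC1 replicate 1 (0.0107), and both astrocyte (0.00340) and neuron genes (0.00608) did without GSC1 replicate 2. Without the 3 short-biased libraries all 3 lists passed toward GSC2 (astrocyte 1.87e-05, neuron 0.00129, mature oligodendrocyte 1.62e-11). The GSC1 tumours left in that fit had brain scores of 5.60 and 4.36, under the 5.81 and 7.21 of the GSC2 tumours. Gja1, the connexin 43 gene of astrocytes, was at 831 ± 152 CPM in GSC1 and 400.3 ± 120.1 CPM in GSC2, and Camk2a, a kinase gene of forebrain neurons, at 156 ± 96.4 against 530.1 ± 291 CPM. Choroid plexus and ependyma genes passed toward GSC2 with 11 of 14 positive (camera adjusted p = 0.000168, and adjusted p = 0.533 with an estimated correlation), but not without GSC2 replicate 3 (adjusted p = 0.0763). Without the 3 short-biased libraries edgeR called 5 members over all genes, Ttr among them, all higher in GSC2. That fit leaves out GSC1 replicate 4, which lay above every GSC2 tumour in each of the 5. Ttr was at 8165 CPM there and at most 4579 CPM in GSC2, so these calls do not hold for all GSC1 tumours. All 8 HOX genes tested had a negative fold (camera adjusted p = 0.00820, and adjusted p = 0.533 with an estimated correlation), and the list was not called without GSC1 replicate 3 (adjusted p = 0.558), without the 3 short-biased libraries (0.128) or with brain score and length offset together (0.117). In these 5 lists 0 genes passed adjusted over the list alone. Imprinted genes had no shared direction (camera adjusted p = 0.791, but toward GSC2 without the 3 short-biased libraries, 7.39e-05), with 3 passing adjusted over the list alone, 2 higher in GSC2 and 1 higher in GSC1. Mest was at 57.4 ± 18.1 against 402 ± 134 CPM and passed with the brain score as a covariate (2.78, SE 0.30), and Peg10 was at 37.7 ± 6.52 against 91.6 ± 36.0 CPM.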

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

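The tests of regional brain genes, of the cell line as the source of the brain markers, of dilution and of other brain regions, and all fits with the brain score or the length offset, were chosen only after the results they bear on had been seen. Genes that the filter on low counts left out of the tests still reached 10 CPM or more in single tumours, 17 such genes in GSC1 replicate 3 and 17 in GSC1 replicate 4, from 26 genes in all, and 0 in the other 5 tumours. The 26 include cerebellar and hindbrain genes, such as Cbln3, Gabra6 and Pcp2 in GSC1 replicate 4 and Hoxb5 and Dbh in both. Among 146 values tested in the 4 GSC1 tumours 1 stood apart from the others of its group by Dixon's test, where chance gives 7.3, or 1 in 20, and 3 GSC2 tumours are too few for that test. It was Plac8, a gene of monocytes and other leukocytes, whose log2 of CPM plus 0.1 was 0.82 in GSC1 replicate 3 and between 2.80 and 3.06 in the other GSC1 tumours.

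Brain cell markers differed between tumours of the same line. Within GSC1 the brain score ranged over 3.47 and the line means differed by 0.43, which restates the pattern and tests no explanation by the line. With the length trend removed the score kept 101% of its range. The trend moved long against short transcripts by -0.70 to 0.64 per library, so its removal could hardly have brought a range of 3.47 down far. The average trend is too small to be the source of that range, and loss particular to single genes was not tested. Of 10 cerebellar genes 6 lay at least 10-fold above every other tumour in GSC1 replicate 4, with Cbln3 at 245 CPM, which is consistent with host brain tissue of differing regions in the sampled material. The labels call that material tumour cells and name no sort, and brain-like differentiation of the tumour cells was not tested.

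Cell cycle genes were low in the tumours with high brain scores. The 9 members with transcripts of at most 2000 bases had a median slope of -0.42 log2 units per unit of score, against -0.56 for all 68, which argues against loss of long transcripts as the whole cause. Dilution of tumour RNA by brain RNA stays open and cannot be told apart from slower division. The mitosis score of GSC2 replicate 2, with a high brain score and no loss of long transcripts, lay 0.47 under that of GSC1 replicate 1, and the slope of members of at least 4000 bases was 1.65 times that of the short ones, so length loss and dilution may both contribute.

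The 114 genes that differed with the brain score as a covariate kept 93.6% of their median fold once the length trend was removed. Length slopes ran from -0.117 to 0.148 log2 units per doubling in GSC1 tumours and from -0.207 to 0.151 in GSC2 tumours. With spans so alike, removing the trend could change folds between the lines only little. It also removes the average trend and no loss particular to single genes, so this cannot decide on length loss as their source. Of the 84 higher in GSC2, 54 had values that did not overlap between the lines. Of the 30 higher in GSC1, 24 (80%, where chance gives 2.86% of genes not picked by a test) had all 4 GSC1 values above all 3 GSC2 values. In 23 of these GSC1 replicates 1 and 2 lay above GSC2 by more than the range within either (Epha3 at 58.9 and 77.3 against at most 8.02 CPM). That argues against hindbrain tissue in GSC1 replicates 3 and 4 as the whole source in the 23. The 30 were picked by a test on these same values, which favours such gaps, so the count is weak evidence. In the 6 whose lines overlap, among them Th at 0.985, 0.662, 29.6 and 12.8 CPM in GSC1 replicates 1 to 4, both replicates 3 and 4 lay above all other tumours, and such tissue cannot be told apart from a difference between the lines, since these genes were picked for low values in replicates 1 or 2. Of the 35 splits of the tumours 2 gave as many genes, the real one with 114 and one with 301, so chance could not be excluded, and that split, which sets the 3 short-biased libraries against the rest and called 3620 genes without a covariate, points to a structure of the samples. With the length offset added, 1 of 35 splits gave as many genes, the real one with 309 against 7 in the highest other, the smallest share that 35 splits can give, but this fit was chosen after seeing the data and its count fell to 1 without GSC2 replicate 1, so the share is no independent test and a difference between the lines stays a hypothesis.

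Without a covariate the real split gave 0 genes, so all 35 splits give as many and their count says nothing about chance. The highest other gave 4310. That highest split sets GSC1 replicates 3 and 4 with GSC2 replicates 2 and 3, the tumours with the highest brain scores, against the rest, which points to a structure of the samples. Of the gene lists, 2 of the 35 splits gave as many, 24 in the real one and 24 in the highest other, so chance could not be excluded. The lowest other split gave 3, so the preset correlation gave list calls for every grouping of these tumours.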

How the results depend on the processing

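The fits with the brain score or the length offset and the fit without the 3 short-biased libraries were chosen after seeing the data. The count of genes that differed between the lines, 0 in edgeR's quasi-likelihood test with 677 at an unadjusted p under 0.05, stayed at 0 with RLE or upper-quartile factors, a mean of at least 5 CPM, a test against a 1.5-fold change, the length offset and each tumour left out. It was 1 with no filter, 1 in limma-voom and 1 with the host covariate, each time Clic5 (adjusted p = 0.0409, 0.0369 and 0.0405, against 0.0801). It was 192 in DESeq2 (88 higher in GSC2, 104 higher in GSC1), 114 with the brain score, 309 with the brain score and length offset, and 55 without the 3 short-biased libraries. The cause was not tested.

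With the brain score as a covariate the 114 genes became 1282 in DESeq2, 12 against a 1.5-fold change and 309 with the length offset, with 86 to 160 under the other settings of normalization, filter, tool and score. Leaving out 1 tumour gave 1 (without GSC2 replicate 1) to 119 (without GSC2 replicate 3). RLE factors moved the split from 84 against 30 to 92 against 50, no filter to 82 against 53, and the host score as a second covariate to 132 against 28. The 309 genes with the length offset as well became 473 with no filter and 558, 36, 20 and 144 without GSC1 replicate 1, 2, 3 and 4, and 1, 106 and 152 without GSC2 replicate 1, 2 and 3. Fewer tumours leave less power, and beyond that the cause was not tested.

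Of the gene lists 24 passed, and 0 with an estimated correlation and 0 in fry, which do not use the preset value. Other factors, filters and the host covariate gave 22 to 26 lists, and leaving out 1 tumour gave 17 (without GSC1 replicate 3) to 26 (without GSC1 replicate 1). Mitosis, E2F and DNA replication, and fibroblast lists were called in the opposite direction without the 3 short-biased libraries. That fit also left out GSC1 replicates 3 and 4, with brain scores of 7.83 and 7.14. The separation of the lines ranged from -4.94 to 11.62 with 1 tumour left out, and was -2.79 over all genes and 0.19 over 2000 genes, none past the threshold. On residuals from the brain score it was 16.38 (one-sided exact permutation p = 0.0286, the smallest that 35 splits can give), a setting that removes only what is linear in the score.

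The replicate numbers did not pair the tumours: deviations of same-numbered tumours correlated at 0.583, -0.306 and 0.409. With the replicate block 0 genes and 22 lists passed, 19 of the 24 among them. Lost with the block were mitosis (adjusted p = 0.295), E2F and DNA replication (0.853), fibroblast (0.953), classical glioblastoma (0.495) and HOX genes (0.112), and gained were mature oligodendrocyte (0.000247), immature neuron (0.00438) and immediate early genes (0.0113). Of 1904 values of 96 named genes under the alternatives, 125 newly passed, with no call in edgeR's test that could be reversed, and 64 values of 14 genes that did not pass differed in sign. Of 490 values of 29 genes in the fit with the brain score, 157 no longer passed, 126 of them with 1 tumour left out, and 0 changed sign. RLE factors moved the median gene by -0.03. With 4 and 3 tumours the main test recovered 0% of simulated 2-fold changes, so changes of that size were below what it can show here.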

Other observations

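The recruited macrophage and neutrophil lists passed a test for change in either direction, but over all 7 tumours no shared direction was called. In that test, fry's mixed test, the recruited macrophage and monocyte list had an adjusted p of 0.00428 and the neutrophil list 0.000474, while camera did not call either (0.0998 and 0.492). The macrophage list was called toward GSC1 without GSC2 replicate 1 (0.00951) or the 3 short-biased libraries (0.0343). Ly6c2, a gene of inflammatory monocytes, was at 3.30 ± 1.22 CPM in GSC1 and 11.1 ± 4.90 CPM in GSC2, Plac8 at 5.96 ± 2.93 against 25.01 ± 9.34 CPM, and Lyve1, a hyaluronan receptor gene, at 1.72 ± 0.704 against 0.487 ± 0.153 CPM. The siderophore-binding gene Lcn2 was at 15.2 ± 14.1 against 82.3 ± 59.6 CPM and S100a8 at 0.334 ± 0.0794 against 0.869 ± 0.284 CPM. Among angiogenic factors, Angpt2 was at 7.38 ± 2.39 against 20.1 ± 4.36 CPM and Pdgfc at 31.3 ± 9.19 against 12.9 ± 2.44 CPM (list camera adjusted p = 0.211). No member of these 3 lists passed edgeR's test or limma-voom over all genes (6, 4 and 3 at an unadjusted p under 0.05 in edgeR), while DESeq2 called 3, 0 and 2, and adjusted over the list alone 3 (2 higher in GSC2, 1 higher in GSC1), 0 and 2 (1 in each direction) did. In the erythroid, forebrain patterning and sex chromosome lists 0 did.

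Erythroid genes were called toward GSC2, with 5 of 7 positive (camera adjusted p = 0.000791, and adjusted p = 0.512 with an estimated correlation), and Alas2, the heme synthesis gene of red cells, was at 3.48 ± 2.85 against 10.9 ± 8.198 CPM. The erythroid list was not called without GSC1 replicate 2 (adjusted p = 0.0684). Forebrain patterning genes were called toward GSC2 with 11 of 21 positive, a median fold of 0.06 and a mean of -0.02 (camera adjusted p = 0.0396, and adjusted p = 0.506 with an estimated correlation), and were not called without GSC1 replicate 3 (0.158), GSC2 replicate 1 (0.0564), GSC2 replicate 2 (0.110) or GSC2 replicate 3 (0.0531). Nkx2-1, a ventral forebrain factor gene, was at 0.236 ± 0.220 against 2.09 ± 0.953 CPM. Notch (camera adjusted p = 0.574), Wnt (0.574), integrin and adhesion (0.574), chemokine and cytokine (0.131), immature neuron (0.0549) and immediate early genes (0.177) did not pass as lists. Of these, immature neuron genes passed toward GSC2 with RLE factors (0.0432), no filter (0.0406) and without GSC1 replicate 1 (0.0370), GSC1 replicate 4 (0.00253) or GSC2 replicate 1 (0.00732), chemokine genes toward GSC2 without GSC1 replicate 1 (0.0197), and immediate early genes toward GSC1 without GSC1 replicate 3 (0.0403), GSC1 replicate 4 (0.0214) or the 3 short-biased libraries (0.00334).

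Genes of the sex chromosomes varied within GSC1. Ddx3y, on the Y chromosome, was at 0.319, 3.53, 0 and 0 CPM in GSC1 replicates 1 to 4 and at 3.71, 5.82 and 3.26 CPM in GSC2 replicates 1 to 3. Xist, the RNA of the inactive X chromosome with a long transcript, was at 132, 229.6, 11.9 and 12.4 CPM and 201, 58.5 and 9.27 CPM in the same order. Eif2s3y, Kdm5d and Uty, also on the Y chromosome, were at 0 CPM in GSC1 replicates 3 and 4 as well. They were at 0.174 to 0.435 CPM in GSC1 replicate 1, and at least 1.51 CPM in GSC1 replicate 2 and 1.48 CPM in each GSC2 tumour. The cause was not tested. The list was called toward GSC2 (camera adjusted p = 0.000268, and adjusted p = 0.506 with an estimated correlation), but not without the 3 short-biased libraries, a fit chosen after seeing the data (adjusted p = 0.242).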
